A study of Mus musculus with 9 samples.

How the data were processed

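RNA sequencing was done on 9 libraries of MMTV-neu mouse mammary tumour cell lines. Per the labels' protocols, cells grew attached in medium with serum, insulin, epidermal growth factor and hydrocortisone, total RNA was extracted with RNeasy columns, first strands were made with oligo-dT primers, and libraries were made with a TruSeq RNA kit. Whether the libraries kept the strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

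The deposited values are FPKM (fragments scaled by transcript length and by the number of mapped fragments) per gene symbol, made by the authors with cutadapt, TopHat2 2.1, Cufflinks 2.2 and Cuffnorm on build mm10, per the submitters' processing notes, which give no order or role. The scaling option, the annotation and any filter are not given in the sources used here. There were 2 tables of 24346 genes. The larger one held all 9 libraries and the smaller one 4 of them with identical values, and every value was read from the larger table. The columns of 33373 and 33377 lack the name suffix that those of the other 7 libraries carry, and their fragment steps on short genes differ, so these 2 libraries may not be on the same scale for every gene. In 27 gene names a spreadsheet had turned the symbol into a date, and 4 of these rows were left out because the name occurred more than once. Of the symbols, 23284 were found in the GENCODE vM21 annotation of GRCm38, which gave the positions.

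FPKM hold no counts, so no count test was used. The value of 1 fragment was recovered from genes under 0.5 FPKM as the most frequent ratio of their values between a library and 45566B wild type, which gives relative depth only. Short noncoding RNA genes (1283 of the genes, with names of microRNA, small nucleolar, Cajal body and U RNA genes) took 5.98 to 14.8% of the summed FPKM of a library. They are shorter than a usual fragment, so their FPKM are large for 1 or a few fragments.

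Genes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with moderated variances that follow the mean, two-sided, and Benjamini-Hochberg adjustment at 0.05. Genes with a mean of at least 1 FPKM over the libraries of a comparison were kept. Log2 fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. Groups were taken from the labelled genotype. The isogenic comparison (45555 and 47298) had the line as a block, the panel comparison (45566B, 33373, 33377 and 46295) had none, and the pairs comparison used the 3 differences within a line, for genes with a mean of at least 1 FPKM in each set of libraries. Below, the isogenic table and the panel table mean the libraries of the isogenic and the panel comparison. In the pairs comparison the libraries of 1 line deviated together, with correlations of 0.706 (45555), 0.391 (47298) and 0.784 (45566B), and the pairing comes from the shared line in the labels.

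The tests, the 24 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The comparison of all 9 libraries, the fits without short noncoding RNA genes, the exact test of list means and the fits without lines 33373 and 33377 were added after. For each comparison the rule named Jak1, the 5 rises and 5 falls with the smallest p where none passed (leaving out microRNA, small nucleolar RNA and unnamed genes), 2 to 4 members with the smallest p of each called list and of 6 lists in any case, and Stat3, Socs3, Cebpd, Bcl3, Erbb2 and Krt8. Not every gene the rule names is reported here. Epcam, Col1a1, Vim and the short noncoding RNA genes were named after their values were seen.

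Lists were written from textbook knowledge and none was chosen on these samples. The list mean of a library is over all measured members, also those under the filter, so its differences are not the mean log2 fold changes of the tested members. They were tested with camera at a preset correlation of 0.01, which compares a list with the other genes, with adjustment over the lists of a comparison. With an estimated correlation, only the interferon-stimulated, interferon gamma-induced and MHC class I lists of the panel table stayed called. fry, which tests whether the members of a list move one way on balance without comparing them with other genes, called the same 3 in the panel table (adjusted p = 0.0070, 0.000201 and 0.0070) and STAT3 targets in the isogenic table (adjusted p = 0.0206). Some lists share members. STAT3 targets hold Lrg1 together with acute-phase genes, Bcl3 and Icam1 together with NF-kappaB targets, and Osmr, Il6st and Il4ra together with cytokine receptors.

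The tests were checked on simulated data, with 200 genes changed in each of 5 simulations and variances drawn from limma's fitted prior. In the isogenic design (11704 genes) no gene was called, so no share of false calls can be given. False calls made up 8.52% of calls in the panel design (11838 genes), 3.53% in the pairs design (10903 genes) and 6.65% over all 9 libraries (12198 genes). In the last design changes of 1, 2 and 4 log2 units were recovered in 24.8%, 62.7% and 89.4% of the changed genes. In every design the changed genes were drawn only from those with a fitted mean log2(FPKM + 1) above 4. In the panel and all-9 designs the libraries of a line were simulated as unrelated. Over all 9 libraries their estimated correlation was 0.702. The shares recovered may thus not hold for lower genes or for these libraries. A list of 30 genes shifted by -2 log2 units was called in 5 of 5 simulations of each design with the preset correlation, and 0 of 100 unshifted lists were. The simulated genes varied independently of each other, so these counts cannot show how the preset correlation behaves with correlated genes. In the libraries themselves, the estimated correlation of the interferon-stimulated list was 0.158 (panel), 0.737 (pairs) and 0.615 (all 9 libraries). The isogenic estimate was 0.0387. That fit has 1 residual degree of freedom, so its estimate depends only on the signs of the residuals and cannot show how correlated the genes are. With an estimated correlation the shifted list was called in 0 of 5 simulations for the isogenic and pairs designs, 4 of 5 for the panel design and 5 of 5 for all 9 libraries, so a lost call in the first 2 of these designs says little.

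The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, rescaling by median ratios (factors 0.995 to 1.02), quantile normalization, variances without a trend, leaving out each line, fits with and without the line as a block, lists without shared genes, and the settings named above as added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out.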

Results

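The series measured gene expression by RNA sequencing in mouse mammary tumour cell lines with and without Janus kinase 1 (JAK1), the kinase that relays signals from interferon receptors and from the gp130 family of cytokine receptors to STAT transcription factors. The lines came from tumours of FVB/N mice with the MMTV-neu transgene, in which a mouse mammary tumour virus promoter drives the rat neu (Erbb2) oncogene in mammary epithelium. There were 9 libraries, 1 for each line and state, of which 5 were labelled Jak1 wild type and 4 Jak1 knockout. Lines 45555, 47298 and 45566B were each present in both states, and their titles name the states Wt and Cre. These 3 lines were grown with puromycin, per the labels' protocols. Lines 33373 and 33377 were present only as wild type and line 46295 only as knockout. The labels name no separate cultures of a line, so each p-value measures only the spread between these libraries.

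The deposited values were FPKM, and the absolute number of fragments behind them is unknown. Summed over genes, a library held between 567483 FPKM (33373) and 721843 FPKM (47298 wild type), and between 10823 and 11624 genes reached 1 FPKM. Low values of a gene were multiples of what 1 fragment is worth, which gave the depth relative to the deepest library, 45566B wild type. It was 0.464 for 45555 wild type, 0.620 for 45555 knockout, 0.606 for 47298 wild type and 0.541 for 47298 knockout. For the other libraries it was 0.661 in 45566B knockout, 0.738 in 33373, 0.767 in 33377 and 0.416 in 46295. On short noncoding RNA genes, 65.5 to 85.7% of the low values of the 7 libraries other than 33373 and 33377 stood at 0.5, 1 or 2 times a shared step. In 33373 only 10.5% of 86 such values did so, and in 33377 9.64% of 83. The libraries of 33373 and 33377, both wild type, thus differed from the other 7 in what 1 fragment was worth on short genes, by a factor that varied from gene to gene, and their relative depths are less certain. Whether they came from a separate library batch or a separate processing run is not given in the sources used here. No knockout library shares this difference, and the panel and all-9 comparisons and the agreement between the tables are also given without these lines.

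Jak1 lies on chromosome 4 from 101152367 to 101265282 on the minus strand in build mm10 and is protein coding. Its level was lower in the knockout library of each isogenic pair, at 86.7 FPKM in wild type and 74.4 in knockout for 45555, 63.1 and 27.5 for 47298, and 16.1 and 14.2 for 45566B. The other wild-type libraries held 19.4 FPKM (33373) and 54.6 FPKM (33377), and 46295 knockout held 22.97 FPKM. The log2 fold change was -0.69 with an SE of 0.36 in the isogenic table (limma, adjusted p = 0.721) and -0.50 with an SE of 0.59 in the panel table (adjusted p = 0.999). Over the 3 pairs it was -0.52 with an SE of 0.26 (adjusted p = 0.771), and over all 9 libraries -0.45 with an SE of 0.62 (adjusted p = 1.000). In the panel table the value was 0.03 without 33377 and 0.16 without 33373 and 33377. A value for the whole gene cannot resolve a deleted part, so these levels check the labels only weakly.

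The lines differed widely in epithelial and mesenchymal genes before any comparison by genotype. Epcam, an adhesion molecule of epithelial cells, stood at 720.1 FPKM in 45566B wild type, 681 in 45566B knockout, 419.8 in 33373 and 524 in 46295, at 2.36 in 33377, and below 1 FPKM in the 4 libraries of 45555 and 47298. Col1a1, a fibrillar collagen chain of fibroblasts, showed the opposite order, with 1879 FPKM in 45555 wild type, 1675 in 45555 knockout and 0.271 in 45566B wild type. In 47298 it went from 1728 FPKM in wild type to 65.5 in knockout. In the same line Krt18, a keratin of simple epithelia, was at 52.7 FPKM in wild type and 250.3 in knockout, and Vim, the mesenchymal intermediate filament, at 2352 and 1189. Erbb2 stood at 37.6 and 243 FPKM in 47298 wild type and knockout, and these values cannot separate the mouse gene from the closely related rat transgene.

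**Figure D1:**
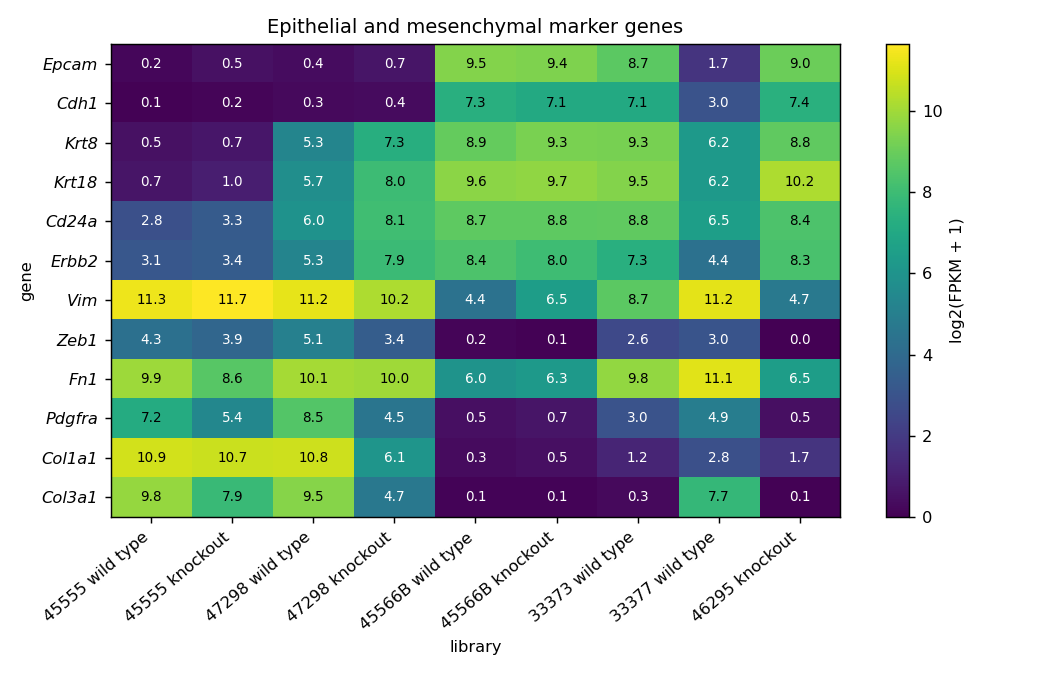
Level of 12 epithelial and mesenchymal marker genes (rows) in the 9 libraries (columns), coloured and printed as log2(FPKM + 1). Lines 45555 and 47298 hold high Vim and almost no Epcam, Col1a1 is high in these lines except in 47298 knockout (65.5 FPKM), lines 45566B, 33373 and 46295 hold high Epcam, and in 47298 Krt18 stands at 52.7 FPKM in wild type and 250.3 in knockout.

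The isogenic table compared the knockout with the wild-type library inside lines 45555 and 47298, which asks what differs with the Jak1 label within a cell line. Several acute-phase, STAT3 target and interferon-stimulated genes had lower values in both knockout libraries, though none passed over all genes. Serpina3n, a protease inhibitor of the acute-phase response, was at 50.9 and 711 FPKM in the wild-type libraries of 45555 and 47298 and at 1.98 and 26.2 in the knockout libraries, a log2 fold change of -4.41 with an SE of 0.29 (n = 2 per state). Il1rn, the secreted antagonist of the interleukin-1 receptor, went from 234 and 343 FPKM to 13.6 and 7.10. Cebpd, a transcription factor induced by STAT3, went from 39.2 and 58.1 FPKM to 3.95 and 3.34.

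No single gene passed in this table. limma called 0 of 11704 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.141, while 761 genes had an unadjusted p under 0.05 against 585 by chance (262 higher and 499 lower). The 5 falls with the smallest p, none past the threshold, were Serpina3n, Scara5 (log2 fold change -2.90, SE 0.25), Cebpd (-3.39, SE 0.31), Il1rn (-4.71, SE 0.46) and Sult1a1 (-2.90, SE 0.30). The corresponding rises were Pcolce2, an enhancer of procollagen processing (2.57, SE 0.24), Fgd3 (2.44, SE 0.37), Atp1b1, a sodium pump subunit (2.00, SE 0.30), Siglecg (1.54, SE 0.25) and Chaf1b, a chromatin assembly factor (1.42, SE 0.23). Serpina3n had an adjusted p of 0.448 and the other 9 an adjusted p of 0.721. In simulated data of this design, 0% of genes shifted by 4 log2 units were recovered, so a count of 0 carries little information here.

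Interferon-stimulated genes fell as a list (camera with a preset correlation, adjusted p = 5.22e-17; adjusted p = 0.697 with an estimated correlation). Of 35 tested members (45 were listed) 34 were lower. Of these, 23 had an unadjusted p under 0.05 and 15 passed adjusted over the list alone, against 0 over all genes. Isg15, a ubiquitin-like modifier, went from 11.96 and 34.8 FPKM to 1.64 and 8.14, and Irf7, the transcription factor that amplifies the interferon response, from 4.18 and 11.6 to 0.226 and 2.49. Ifitm3, a membrane protein that restricts virus entry, was at 1093 and 1849 FPKM in wild type and at 201 and 308 in knockout. Among the interferon gamma-induced genes 10 of 12 were lower, 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone, and the list fell (adjusted p = 0.000118; adjusted p = 0.697 with an estimated correlation). Its member Irgm2, an immunity-related GTPase, had a log2 fold change of -1.49 (SE 0.29). MHC class I antigen presentation was not called (adjusted p = 0.504), with 14 of 21 members lower and list means that differed by -0.69 in 45555 and 0.50 in 47298.

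STAT3 targets fell as a list (adjusted p = 0.00037; adjusted p = 0.697 with an estimated correlation), with 20 of 28 members lower and 8 higher. Adjusted over the list alone, 5 were lower and 1 higher, against 0 over all genes. Besides Cebpd, the members with the smallest p were Fos, an immediate-early transcription factor (log2 fold change -3.22, SE 0.41), Bcl3 (-1.66, SE 0.27) and Osmr, the oncostatin M receptor (-1.83, SE 0.31). Socs3, the feedback inhibitor of gp130 signalling, was at 10.4 and 24.1 FPKM in wild type and 4.55 and 2.37 in knockout. Acute-phase genes also fell (adjusted p = 0.000311; adjusted p = 0.697 with an estimated correlation), with 11 of 14 lower and 5 of these adjusted over the list alone. Mt2, a metallothionein, had a log2 fold change of -2.48 (SE 0.44), and Hp, haptoglobin, of -3.95 (SE 0.78). The JAK and STAT genes themselves fell as a list (adjusted p = 0.0159; adjusted p = 0.697 with an estimated correlation), with 7 of 10 lower and 0 adjusted over the list alone. Stat2 had a log2 fold change of -1.54 (SE 0.25), and Stat3 went from 66.5 and 92.3 FPKM to 19.0 and 46.0. Cytokine receptors that signal through JAK1 fell too, with 12 of 15 lower and Lifr at -2.10 (SE 0.58; camera adjusted p = 0.00302; adjusted p = 0.697 with an estimated correlation).

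Proliferation genes rose as a list (camera adjusted p = 6.89e-17, or 0.697 with an estimated correlation). All 28 were higher in knockout on average, and 27 of them in both lines. At an unadjusted p under 0.05 there were 18, and adjusted over the list alone 0. The replication helicase subunits led, with Mcm2 at 24.02 and 11.3 FPKM in wild type and 71.0 and 29.7 in knockout, a log2 fold change of 1.42 (SE 0.24), Mcm5 at 1.49 (SE 0.28), Mcm3 at 1.27 (SE 0.29) and Mcm6 at 1.18 (SE 0.27). NF-kappaB targets fell (14 of 18 lower, 0 adjusted over the list alone, adjusted p = 0.00886; adjusted p = 0.697 with an estimated correlation), with Birc3, an inhibitor of apoptosis, at -1.03 (SE 0.25).

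Markers of other cell types moved in the same table. Fibroblast markers fell (11 of 12 lower, adjusted p = 9.11e-05), as did adipocyte markers (6 of 6 lower, adjusted p = 0.00949), while luminal epithelial markers rose (9 of 10 higher, adjusted p = 0.0248). Each of the 3 had an adjusted p = 0.697 with an estimated correlation and 0 members adjusted over the list alone. Most of this came from line 47298, where the list means differed by -2.37, -2.69 and 0.46, against -0.60, -0.07 and 0.02 in 45555. Pdgfra, a receptor for platelet-derived growth factor, was at 143 and 41.3 FPKM in the wild-type and knockout libraries of 45555 and at 373 and 22.4 in those of 47298. Fabp4, a fatty acid-binding protein of adipocytes, was at 331 and 311 FPKM in the wild-type and knockout libraries of 45555 and at 885 and 15.5 in those of 47298. Not called were the lists of mesenchymal genes (camera adjusted p = 0.137), hypoxia and glycolysis genes (0.184), ErbB family and ligands (0.0743) and p53 targets (0.262). Nor were basal and myoepithelial markers (0.262), endothelial markers (0.270), gp130 ligands (0.424) and STAT5 targets and milk protein genes (0.451). The same held for BCL2 family and caspases (0.451), mitochondrial respiratory chain genes (0.451), ERK pathway output genes (0.455) and immune cell markers (0.960, 1 member tested).

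**Figure D2:**
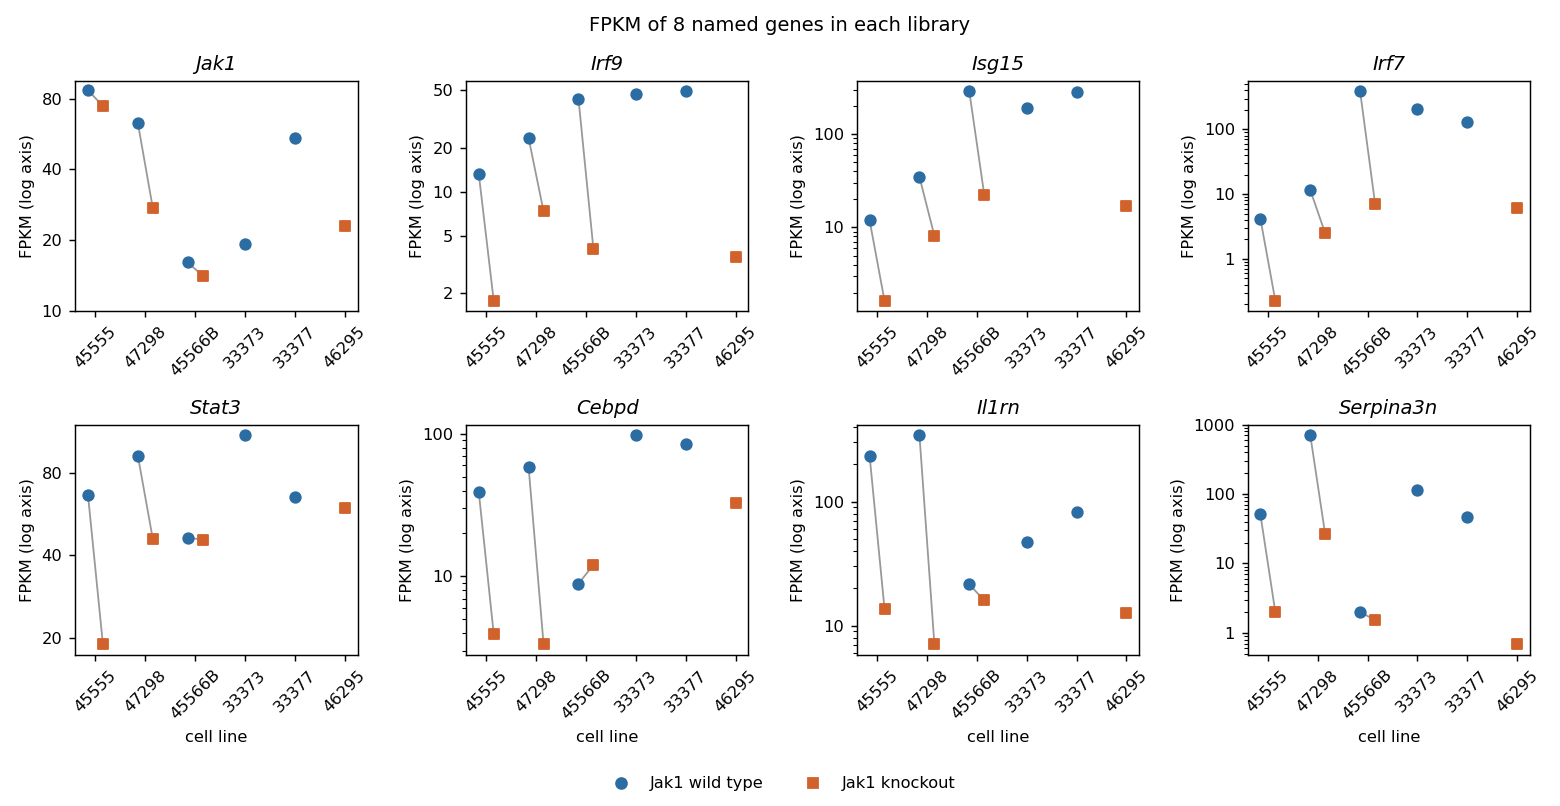
FPKM (log axis) of 8 genes in each library by cell line, with blue circles for Jak1 wild type, orange squares for Jak1 knockout and grey lines joining libraries of 1 line. Isg15 and Irf9 lie lower in the knockout library of all 3 pairs, whereas Cebpd does so in 45555 and 47298 but is at 8.89 FPKM in wild type and 12.1 in knockout in 45566B.

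The panel table set 2 knockout libraries (45566B and 46295) against 3 wild-type libraries (45566B, 33373 and 33377), which asks how knockout tumour lines differ from largely unrelated wild-type lines. The interferon programme was far lower in the knockout libraries. Irf9, the DNA-binding subunit of the ISGF3 complex, was at 43.7, 47.2 and 49.2 FPKM in wild type and at 4.03 and 3.58 in knockout, a log2 fold change of -3.31 with an SE of 0.22 (n = 3 and 2). Isg15 was at 287, 191 and 285 FPKM in wild type and at 22.4 and 17.0 in knockout (-3.61, SE 0.29). Iigp1, an interferon-inducible GTPase, had a log2 fold change of -4.69 (SE 0.38). Ccl5, a chemokine, was higher, at 44.6, 13.1 and 15.7 FPKM in wild type and 204 and 128 in knockout (2.88, SE 0.59).

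limma called 0 of 11838 genes, with a smallest adjusted p of 0.0749 and 215 genes at an unadjusted p under 0.05 against 592 by chance (58 higher and 157 lower). The 5 falls with the smallest p were all interferon-stimulated, namely Irf9, Ifi44 (log2 fold change -4.20, SE 0.32), Isg15, Xaf1, a proapoptotic interferon target (-3.38, SE 0.28), and Irgm2 (-3.22, SE 0.26), each with an adjusted p of 0.0749. With a pseudocount of 0.1 in place of 1, Irf9 passed (adjusted p = 0.0450, in a range of 0.0450 to 0.485 over its tested alternatives). The rises with the smallest p were Ccl5 (adjusted p = 0.707), Dgkk, a diacylglycerol kinase (3.15, SE 0.67), Acsbg1, an acyl-CoA synthetase (2.03, SE 0.48), Fxyd6 (3.06, SE 0.74) and Depdc7 (1.52, SE 0.37). Simulated changes of 2 and 4 log2 units were recovered in 9.25% and 72.4% of the changed genes, all well above the filter, at this design.

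All 45 members of the interferon-stimulated list were lower, 41 at an unadjusted p under 0.05 and 41 adjusted over the list alone, against 0 over all genes, and the list fell (adjusted p = 4.5e-81; adjusted p = 0.0298 with an estimated correlation). In 42 of them both knockout libraries lay below all 3 wild-type libraries, for which chance gives a share of 0.1. Of 17 interferon gamma-induced genes 16 were lower and 11 adjusted over the list alone (adjusted p = 2.45e-28; adjusted p = 0.0265 with an estimated correlation), with Gbp9 at -3.33 (SE 0.29) and Gbp2 at -2.50 (SE 0.25), both guanylate-binding proteins. MHC class I genes fell as well, with 23 of 23 lower and 16 adjusted over the list alone (adjusted p = 8.32e-28; adjusted p = 0.0265 with an estimated correlation). H2-K1, a classical class I heavy chain, was at 622, 513 and 411 FPKM in wild type and 160.5 and 195 in knockout, and Tap1, the peptide transporter, had a log2 fold change of -1.98 (SE 0.34). These 3 lists were also the ones called without 33373 and 33377, where their mean log2 fold changes were -3.18, -2.72 and -1.29, each with an adjusted p of 0.833 with an estimated correlation in that smaller fit.

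Without the wild-type lines 33373 and 33377, the mean log2 fold changes of the other called lists of the panel table shrank or changed sign. STAT3 targets fell with 25 of 29 lower (mean log2 fold change -0.60, adjusted p = 0.000954; adjusted p = 0.526 with an estimated correlation), and acute-phase genes with 18 of 18 lower (-1.76, adjusted p = 3.55e-05; adjusted p = 0.526 with an estimated correlation). Both lists had 0 members adjusted over the list alone. Without both lines these means were 0.27 and -0.08 and neither list was called. Cebpd was at 8.89, 98.1 and 84.6 FPKM in wild type and at 12.1 and 32.5 in knockout, so the 45566B pair did not follow the group difference. Stat3 was at 46.4 and 45.7 FPKM in that pair. The JAK and STAT list fell (adjusted p = 0.00358; adjusted p = 0.563 with an estimated correlation) with 6 of 10 lower and 2, among them Stat2 (-2.88, SE 0.29), adjusted over the list alone. It was not called without both lines, at a mean of -0.25, but inside the 45566B pair its list mean differed by -0.56.

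Cell-type lists differed with the same lines. Mesenchymal genes (21 of 23 lower, adjusted p = 3.63e-05), fibroblast markers (9 of 9 lower, adjusted p = 0.000129) and adipocyte markers (2 of 2 lower, adjusted p = 0.0376) fell, each with an adjusted p = 0.526 with an estimated correlation. Luminal epithelial markers rose (20 of 21 higher, adjusted p = 0.00131; adjusted p = 0.746 with an estimated correlation), as did proliferation genes (22 of 28 higher, adjusted p = 0.00707; adjusted p = 0.879 with an estimated correlation), and hypoxia and glycolysis genes fell (17 of 22 lower, adjusted p = 0.00236; adjusted p = 0.617 with an estimated correlation). Each had 0 members adjusted over the list alone. None of these 6 was called without 33373 and 33377, and the luminal mean was -0.01 without 33377 and the proliferation mean -0.10 without 33373. Axl, a receptor tyrosine kinase of mesenchymal cells, was at 51.1, 144 and 246 FPKM in wild type and 55.0 and 2.06 in knockout. The remaining 12 lists were not called, with adjusted p-values from 0.162 for cytokine receptors that signal through JAK1 to 0.868 for p53 targets.

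**Figure D3:**
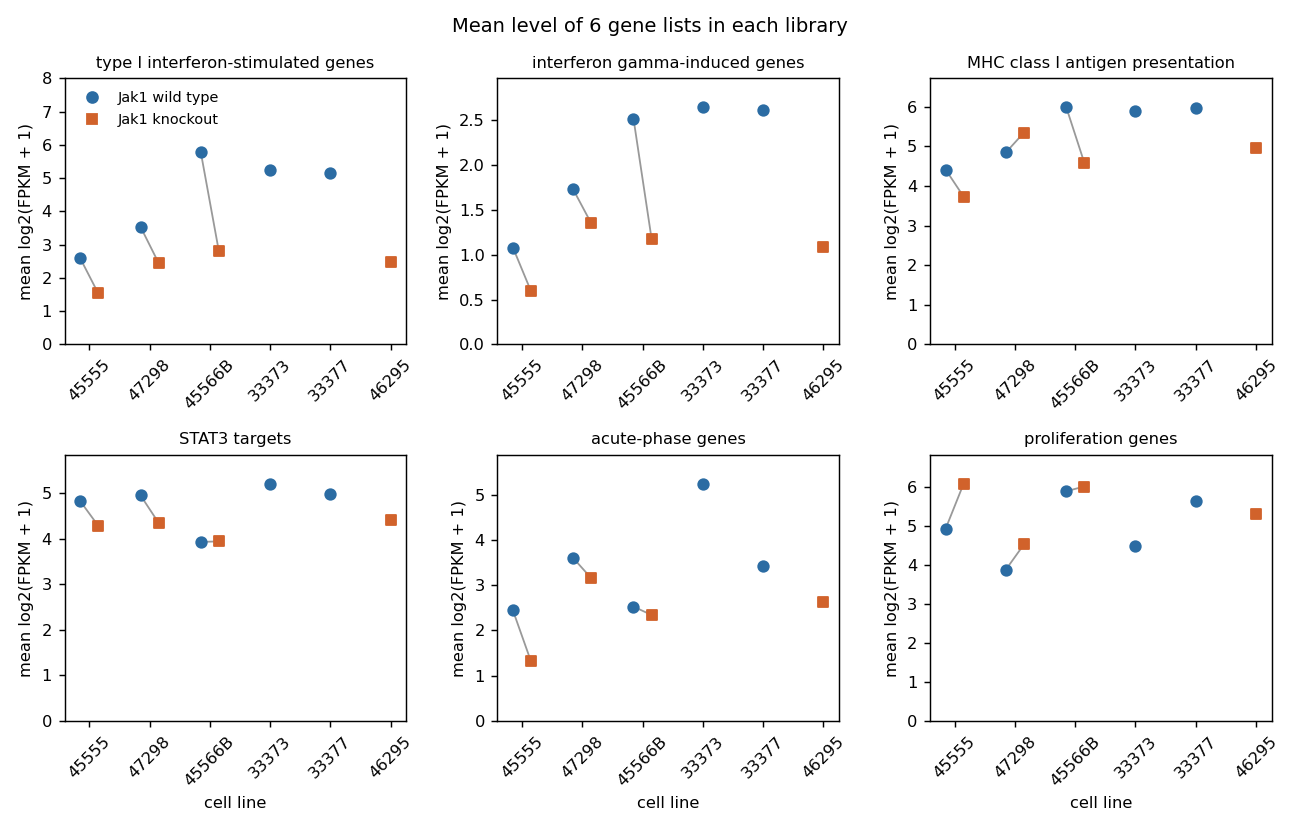
Mean log2(FPKM + 1) of 6 gene lists in each library by cell line, with blue circles for Jak1 wild type, orange squares for Jak1 knockout and grey lines joining libraries of 1 line. Interferon-stimulated genes lie between 2.59 and 5.78 in wild type and between 1.53 and 2.80 in knockout, and the knockout library is the lower one in each of the 3 pairs.

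Within the 3 isogenic pairs, which ask for a change shared by 45555, 47298 and 45566B, the mean of the interferon-stimulated list was again lower in each knockout library. Ifitm3 was at 1093, 1849 and 2774 FPKM in the wild-type libraries of 45555, 47298 and 45566B and at 201, 308 and 352 in their knockout libraries, a log2 fold change of -2.66 with an SE of 0.23 (n = 3 pairs). Ifi27 (-1.62, SE 0.20), Ifit1 (-1.66, SE 0.21) and Ifi204 (-2.03, SE 0.27), all interferon-induced, and Clec2d, a ligand of a natural killer cell receptor (-1.47, SE 0.16), followed. Higher in all 3 knockout libraries were Prss23, a serine protease (0.98, SE 0.16), Acsbg1 (1.15, SE 0.20), Pcolce2 (2.08, SE 0.37), Pdgfa, a platelet-derived growth factor (1.13, SE 0.22), and Ckap2, a spindle protein (0.75, SE 0.15).

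These 10 genes were those with the smallest p in each direction, each at an adjusted p of 0.771, and limma called 0 of 10903 genes. There were 431 at an unadjusted p under 0.05 against 545 by chance, 197 higher and 234 lower. Simulated changes of 1, 2 and 4 log2 units were recovered in 0.299%, 51.3% and 89.1% of the changed genes, all well above the filter, at this design.

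Interferon-stimulated genes fell as a list, with 35 of 35 members lower on average and 26 adjusted over the list alone (adjusted p = 3.74e-31; adjusted p = 0.585 with an estimated correlation). In all 3 pairs 30 of them were lower, and 5 were not lower in 47298. The list mean, members under the filter included, differed by -1.06 in 45555, -1.09 in 47298 and -2.98 in 45566B, a mean of -1.71 ± 1.10 (SD, n = 3). Over the 35 tested members alone it differed by -1.31, -1.26 and -3.01. Interferon gamma-induced genes fell with 10 of 11 lower and 7 adjusted over the list alone (adjusted p = 1.77e-08), led by Gbp2 (-1.79, SE 0.26). The JAK and STAT genes fell (7 of 10 lower, adjusted p = 0.00501) with 1, Stat2 (-1.87, SE 0.28), adjusted over the list alone, and their list mean was lower in all 3 pairs, by -0.60, -0.45 and -0.56. Proliferation genes rose with 28 of 28 higher on average (camera adjusted p = 9.6e-15). Of these, 14 were higher in all 3 pairs and 0 passed adjusted over the list alone. Their list mean differed by 1.16 in 45555, 0.65 in 47298 and 0.12 in 45566B, and Ccnb2, a mitotic cyclin, was at 0.65 (SE 0.15). Mcm2, Mcm3, Mcm5 and Mcm6, which led in the isogenic table, differed by -0.08, -0.12, -0.12 and -0.37 in 45566B. These 3 lists each had an adjusted p = 0.585 with an estimated correlation.

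In other lists the pairs differed in size or direction. STAT3 targets (20 of 28 lower, adjusted p = 0.00111) and acute-phase genes (11 of 14 lower, adjusted p = 0.000603) fell, but the STAT3 list mean differed by -0.54, -0.60 and 0.01 and the acute-phase mean by -1.13, -0.45 and -0.19 in 45555, 47298 and 45566B. MHC class I genes fell with 18 of 21 lower (adjusted p = 0.000603), at -0.69, 0.50 and -1.40. Each of these 3 had an adjusted p = 0.585 with an estimated correlation and 0 members adjusted over the list alone. The same held for cytokine receptors that signal through JAK1 (11 of 12 lower, adjusted p = 0.00197), fibroblast markers (8 of 9 lower, adjusted p = 0.00219), hypoxia and glycolysis genes (13 of 21 lower, adjusted p = 0.0102) and NF-kappaB targets (13 of 18 lower, adjusted p = 0.0445), which fell, and for luminal markers (8 of 9 higher, adjusted p = 0.0115) and p53 targets (13 of 19 higher, adjusted p = 0.0445), which rose. Ccnd1, a G1 cyclin on the STAT3 list, was higher, at 105, 166 and 411 FPKM in wild type and 329, 933 and 485 in knockout. Without 47298 the number of called lists was 8 in place of 13. The other 11 lists were not called, with adjusted p-values from 0.0596 for adipocyte markers to 0.801 for STAT5 targets and milk protein genes.

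**Figure D4:**
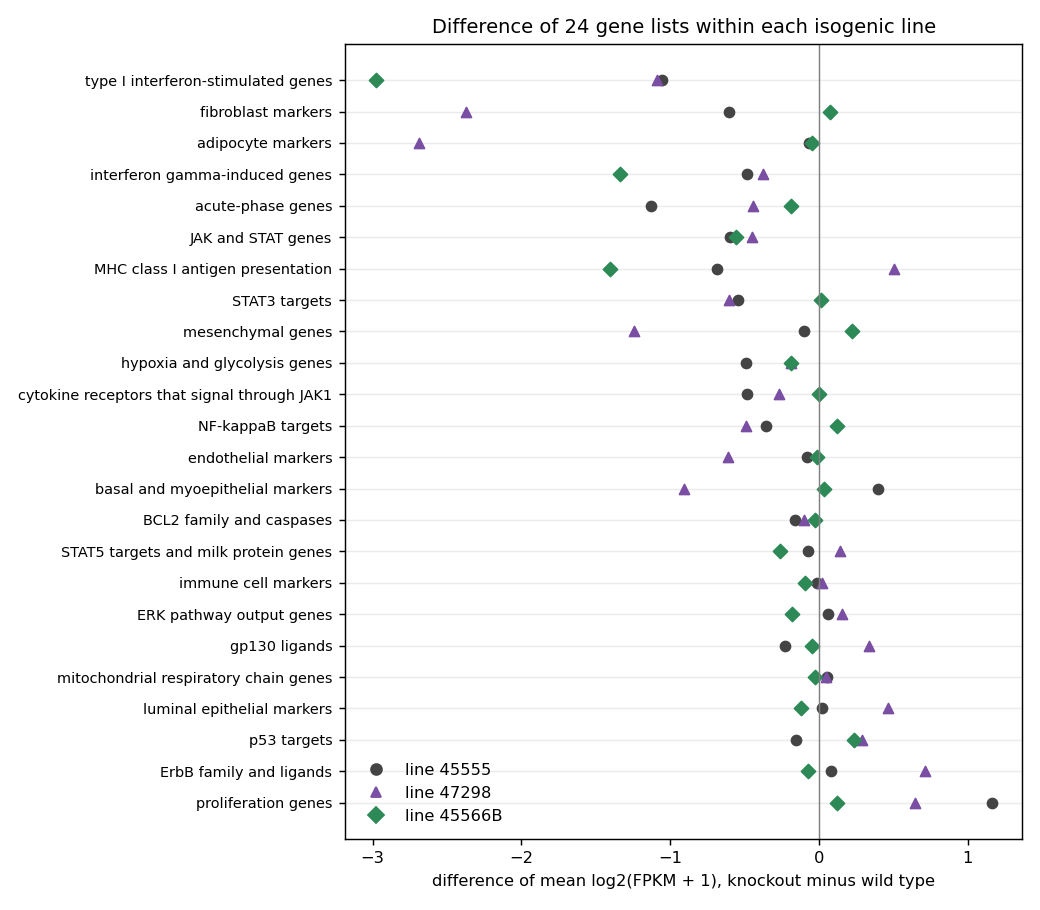
Difference of the mean log2(FPKM + 1) between the knockout and the wild-type library of each isogenic line for 24 gene lists (1 symbol per line, the vertical line at 0). Interferon-stimulated genes lie at -1.06, -1.09 and -2.98 and proliferation genes at 1.16, 0.65 and 0.12 in 45555, 47298 and 45566B, while fibroblast markers reach -2.37 in 47298 alone.

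The isogenic and panel comparisons share no library, so their agreement was tested gene by gene. Stat2, Irf7, Isg15 and other interferon genes were lower in both, but across all 10903 genes tested in both the log2 fold changes had a Spearman correlation of 0.0894 and 51.5% had the same sign. As 0 genes passed in either table, overlap was counted at an unadjusted p under 0.05. Lower in both were 36 genes against 5.05 by chance (Fisher's exact test, one-sided p = 2.59e-21), of which 26 were on an interferon list, and higher in both were 2 against 0.947 (one-sided p = 0.244). Another 7 went opposite ways. Genes are not independent replicates, so these p-values describe overlap within these libraries. A test of the difference between the tables' effects called 5 of 12198 genes, Snord49b, Snord34, Snora30, Mir7025 and Mir1247, all short noncoding RNAs. This test had no line block, so it took the libraries of a line as independent. It gave for the interferon-stimulated list a difference, isogenic minus panel, of 1.70 log2 units (camera adjusted p = 4.65e-22; adjusted p = 0.509 with an estimated correlation). Called as well were interferon gamma-induced genes (1.45, adjusted p = 1.55e-08; adjusted p = 0.509 with an estimated correlation), MHC class I genes (1.13, adjusted p = 6.16e-09; adjusted p = 0.902 with an estimated correlation) and proliferation genes (0.58, adjusted p = 0.0034; adjusted p = 0.934 with an estimated correlation). Without 33373 and 33377 the Spearman correlation was -0.20, with 41.3% of 10531 genes of the same sign, 34 lower in both against 4.01 by chance and 0 higher in both. The difference for the interferon-stimulated list was then 2.09 (camera adjusted p = 1.14e-21, or 0.5004 with an estimated correlation), and 20 genes were called, all short noncoding RNAs. Also called with the preset correlation were interferon gamma-induced (1.53), MHC class I (1.17), proliferation (1.13), luminal (0.46) and ERK pathway output genes (0.33). Called with a negative difference were fibroblast (-2.20) and adipocyte markers (-2.06), acute-phase (-1.30) and mesenchymal genes (-0.85), STAT3 targets (-0.87) and NF-kappaB targets (-0.72). With an estimated correlation no list was called.

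A comparison of all 9 libraries, 5 wild type against 4 knockout, was added after the larger table was seen to hold them all. Irf9 had a log2 fold change of -2.77 with an SE of 0.45 (n = 5 and 4), Sp100, an interferon-induced nuclear body protein, of -2.998 (SE 0.49), Ube2l6, the conjugating enzyme for Isg15, of -2.47 (SE 0.42), Ifi203 of -2.48 (SE 0.43), each with an adjusted p of 0.851 in limma's test, and Lgals3bp of -2.99 (SE 0.55). Acsbg1 was higher at 1.59 (SE 0.33), followed by the chaperone Hspa4 (0.54, SE 0.19), Fam216a (0.46, SE 0.15), Cars2 (0.46, SE 0.17) and Gnl3l (0.38, SE 0.15). limma called 0 of 12198 genes, with 144 at an unadjusted p under 0.05 against 610 by chance (27 higher and 117 lower). With the line as a random block it called 0 as well, with 804 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0818.

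Interferon-stimulated genes fell as a list, with 44 of 44 lower and 25 adjusted over the list alone (adjusted p = 6.3e-65; adjusted p = 0.0717 with an estimated correlation). Interferon gamma-induced genes (17 of 18 lower, 10 adjusted over the list alone, adjusted p = 3.43e-21) and STAT3 targets (23 of 29 lower, 0 adjusted over the list alone, adjusted p = 8.04e-07) also fell, both with an adjusted p = 0.0717 with an estimated correlation. The interferon-stimulated list mean was 4.46 ± 1.34 in wild type (SD, n = 5) and 2.32 ± 0.55 in knockout (SD, n = 4), a difference of -2.15 with a two-sided exact permutation p of 0.0317, or 0.619 adjusted over 24 lists. The smallest p this design allows is 0.00794, and the test exchanges libraries freely, although 3 lines supply both states. A sign-flip test that keeps the 3 pairs cannot give a p under 0.25. Without 33373 and 33377 the means were 3.97 ± 1.64 (n = 3) and 2.32 ± 0.55 (n = 4), and the exact permutation p was 0.0571, where 0.0286 is the smallest possible. The wild-type library of 45555, at 2.59, lay below the knockout library of 45566B, at 2.80.

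Acute-phase genes fell (17 of 18 lower, adjusted p = 1.77e-08; adjusted p = 0.181 with an estimated correlation), as did MHC class I genes (20 of 22 lower, adjusted p = 4.92e-12) and JAK and STAT genes (7 of 10 lower, adjusted p = 0.000277), both with an adjusted p = 0.267 with an estimated correlation. B2m, the light chain of class I molecules, had a log2 fold change of -1.22 (SE 0.51) and Il1rn of -2.87 (SE 0.76). Proliferation genes rose with 28 of 28 higher (adjusted p = 2.56e-09) and NF-kappaB targets fell with 17 of 23 lower (adjusted p = 0.00599), both with an adjusted p = 0.474 with an estimated correlation. Cytokine receptors that signal through JAK1 (12 of 16 lower, adjusted p = 0.00399; adjusted p = 0.303 with an estimated correlation) fell. So did fibroblast markers (12 of 12 lower, adjusted p = 0.00581), mesenchymal genes (22 of 26 lower, adjusted p = 0.0129) and hypoxia and glycolysis genes (21 of 22 lower, adjusted p = 0.0185), each with an adjusted p = 0.582 with an estimated correlation. Without 33373 and 33377, NF-kappaB targets (mean log2 fold change -0.08, adjusted p = 0.530), mesenchymal genes (-0.89, adjusted p = 0.114) and hypoxia and glycolysis genes (-0.27, adjusted p = 0.345) were not called. With all 9 libraries JAK and STAT genes had 2 members adjusted over the list alone and the other 8 lists of this paragraph 0. The remaining 12 lists were not called, with adjusted p-values from 0.0583 for adipocyte markers to 0.974 for STAT5 targets and milk protein genes.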

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

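All tests of explanations in this part were chosen only after the results were seen, as were the counts of splits over all 9 libraries. A sample standing apart was looked for in 64 groups of 4 or 5 libraries, of which chance singles out about 1 in 20.

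Bcl3, a partner of NF-kappaB that STAT3 induces, stood apart in the 45555 knockout library at 1.06 FPKM, where the nearest of the other 3 knockout libraries held 4.96. The mean log2(FPKM + 1) of the endothelial markers stood apart in 47298 wild type at 1.08, where the nearest of the other 4 wild-type libraries was at 0.43. In 5 short noncoding RNA genes, named after their values were seen, the effects differed between the isogenic and the panel tables in a test of the difference itself (limma, with no line block). The differences, isogenic minus panel, were 16.09 log2 units for Snord49b (adjusted p = 0.00215), -7.46 for Mir7025 (adjusted p = 0.00332), -6.12 for Mir1247 (adjusted p = 0.00758), -10.47 for Snord34 (adjusted p = 0.00758) and 9.30 for Snora30 (adjusted p = 0.0146). Each of these genes was listed at 0 in several libraries, so the differences depend on the pseudocount.

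The values of these short RNA genes were those of very few fragments. Mir7025 was at 141 and 217 FPKM in the wild-type libraries of 45555 and 47298 and listed at 0 in the other 7 libraries. Of 21 values above 0 over the 5 genes, 13 were compared with the smallest of their gene after scaling by relative depth, with the step read separately for 33373 and 33377. Within 3%, 100% of these 13 equalled the smallest or were a higher whole multiple of it. The largest multiple was 5. Differences between 0 and a few fragments are thus a candidate explanation, and no biological explanation was tested for them.

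The mean of the interferon-stimulated list was lower in the knockout library of all 3 isogenic lines, and 30 of 35 members were lower in all 3. A library batch or separate processing of 33373 and 33377 is argued against as the whole explanation, because the difference nearest 0 among the isogenic lines, which hold neither library, was -1.06 (45555). Leukocytes in the wild-type cultures are argued against as well, since Ptprc, Cd52, Laptm5, Tyrobp and Coro1a reached at most 0.480 FPKM in a wild-type library, and 4 of 18 immune markers reached 1 FPKM in any of these. An effect of the Cre vector in place of the genotype cannot be told apart from loss of Jak1 in the 3 pairs. Line 46295, whose label names no Cre, had a list mean of 2.48, a difference of -0.11 from the lowest wild-type library (45555, 2.59). The other wild-type libraries were at 3.54 (47298), 5.16 (33377), 5.25 (33373) and 5.78 (45566B). Across genes 46295 correlated at 0.869 with 33373, 0.849 with 45566B wild type and 0.639 with 45555 wild type. As 46295 is 1 library without a pair, it cannot settle this. Loss of JAK1 signalling from interferon receptors is consistent with the lower levels but stays a hypothesis, with the vector open.

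The libraries of line 47298 differed in epithelial and fibroblast genes far more than those of the other lines. A swap of the wild-type libraries of 45555 and 47298 is argued against, since 45555 wild type correlated across genes at 0.798 with 47298 knockout and at 0.921 with its own knockout library. A wrong label of a single 47298 library stays open and was not tested, since 47298 wild type correlated at 0.832 with its own knockout library, 0.837 with 45555 knockout and 0.890 with 45555 wild type, and 47298 knockout at 0.854 with 33377. Whether a mixture of 2 kinds of cells in the 47298 wild-type culture contributed cannot be decided here. Among 85 genes abundant in 47298 knockout and nearly absent from 45555, the wild-type level was a median of 0.166 times the knockout level. The log2 interquartile range was 0.68, against 1.04 to 8.42 in 36 comparisons between different lines. Between the libraries of 45566B it was 0.49 and 0.76, so a narrow range also occurs within a line and does not single out a mixture. The opposite ratio in 47298, over 37 genes abundant in wild type, had a median of 0.0658 and a range of 6.83. Most of these 37 were thus low in both 45555 and 47298 knockout, which a mixture of such cells alone would not give. Over 83 genes abundant in 45555 and low in 47298 knockout, 47298 wild type stood at a median of 0.763 times 45555 (quartiles 0.465 and 1.26). Loss of Jak1 raising epithelial genes stays open, as the luminal list was higher by at least 0.2 in 1 of 3 lines (47298).

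The splits of the libraries bear on the counts of genes and lists. For the 3 pairs there are only 10 splits, too few for a share under 0.05. The real split called 0 genes (limma, 431 at an unadjusted p under 0.05) and the highest other 274. With a real count of 0, 10 of 10 is the only possible outcome, so it says nothing about chance. For lists the real split called 13 and the highest other 8, and 1 of 10 splits reached the real count. Among the 4 splits that part all 3 pairs, the others reached at most 8 lists and 2 genes. Over all 9 libraries, 100 splits were drawn from all possible ones. The real split called 0 genes (limma, 144 at an unadjusted p under 0.05) and the highest other 1895, and 100 of 100 is again the only possible outcome. It called 12 lists, the highest other 15, and 9 of 100 reached 12, so chance is not excluded when all of these splits are counted. Among the 24 splits that part all 3 pairs as the real one does, 1, the real one, reached 12, and the highest other called 11. The split with 1895 genes set the 45566B pair, 33373 and 46295 apart, and another with 820 genes set the pairs of 45555 and 47298 apart, which points to a structure of the samples by line and cell state.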

How the results depend on the processing

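The settings for all 9 libraries, the exact permutation of list means and the fits without 33373 and 33377 were chosen only after the results were seen. For the values below the cause was not tested unless stated. Of the values compared under an alternative, 145 of 168 for counts, agreement and Jak1 stayed, 20 moved and 3 reversed. A count, share or correlation was taken as staying when it lay within a set factor of the reported one, so staying does not mean equal. For lists 541 of 699 stayed, 150 became weaker and 8 reversed, and for named genes 2818 of 2840 stayed, 21 reversed and 1 became stronger. As no gene was called as reported, a named gene or Jak1 could not become weaker. For these genes, staying means only that the sign was kept without a new call, whatever the change in size, so the share says little about robustness.

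Interferon-stimulated genes were called in the panel table in all 15 alternatives, with a mean log2 fold change of -3.21 to -2.59. In the isogenic table the mean was -1.71 to -1.07, and the call was lost with an estimated correlation and with fry.

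Genes called, 0 as reported by limma, were 4 in the isogenic table with a pseudocount of 0.1, 3 with a mean of at least 5 and 6 with no line block, all short noncoding RNAs. In the panel table a pseudocount of 0.1 gave 4, namely Irf9 and 3 short noncoding RNAs. Leaving out a line gave 0 to 10 over the pairs (10 without 47298) and 0 to 2 over all 9 libraries (2 without 45555, 1 without 45566B), all short noncoding RNAs.

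Lists called with an estimated correlation and with fry were 0 and 1 in place of 11 in the isogenic table, 3 and 3 in place of 12 in the panel table, 0 and 0 in place of 13 over the pairs, and 0 and 0 in place of 12 over all 9 libraries. The exact permutation of list means called 0 over all 9. Leaving out a line gave 8 to 13 lists over the pairs, with 8 without 47298. The panel table gave 3 without 33373 and 33377, a fit with fewer samples.

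Leaving out lines, log2 values spanned -1.91 to 0.14 for Psmb9 in the isogenic table. In the panel table they spanned -0.82 to 0.030 for Jak1, -0.33 to 1.35 for Jak2, -0.042 to 1.47 for Krt8, -0.0080 to 2.104 for luminal epithelial markers, panel table, and -0.10 to 0.68 for proliferation genes. Erbb2 over the pairs spanned -0.051 to 1.45 and Krt8 over all 9 libraries -0.29 to 1.28.

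The 45566B pair alone reversed these panel values: Jak2 -0.25, Pim3 -0.11, Axl 0.10, Fn1 0.30, Cebpd 0.40, Bcl3 0.31 and Erbb2 -0.35. Without 33373 and 33377 the reversed panel values were 0.16 for Jak1, 0.17 for Stat3, 0.017 for Steap4, -0.41 for Esrp1, -0.060 for Grhl2, 0.38 for Fn1, 1.18 for Socs3, 1.08 for Cebpd, 0.26 for Bcl3 and -0.22 for Erbb2. The list means were 0.27 for STAT3 targets, -0.12 for luminal markers, 0.26 for mesenchymal genes, 1.31 for fibroblast markers, -0.23 for proliferation genes and 0.10 for hypoxia and glycolysis genes. In this fit the filter left 2 fibroblast markers and 15 mesenchymal genes, against 9 and 23 with both lines, so these 2 changes of sign are over different sets of genes. The mean log2(FPKM + 1) of all fibroblast markers was 0.155 in 45566B wild type, 0.227 in 45566B knockout and 0.532 in 46295.

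Between the isogenic and panel tables, the same sign was found in 84.4% of 45 genes at an unadjusted p under 0.05 in both, in place of 51.5% of all, and rho was 0.0524 with a mean of at least 5 in place of 0.0894. Without 33373 and 33377 rho reversed to -0.20, with 41.3% of the same sign, so the direction of this correlation rested on these lines.

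Not run were the count-based alternatives, since FPKM hold no counts, and the panel fit with the line as a random block, whose correlation could not be estimated from 1 pair. Leaving out a line of the isogenic table leaves no residual degrees of freedom, so it gave values with no test. Where a group is left with 1 library, that library is assumed to vary like the others. The absolute depth is unknown, so what it limits cannot be given in fragments.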

Other observations

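Some lists had a mean, median and test that differed in sign, none of them called. For ERK pathway output genes in the isogenic table the mean log2 fold change was 0.11 and the median -0.16, and over the 3 pairs 0.01 and -0.15. For STAT5 targets and milk protein genes over all 9 libraries the mean was -0.12 and the median 0.33, and for p53 targets -0.01 and 0.12. The 1 immune cell marker tested in the isogenic table had a log2 fold change of -0.01 where the test pointed up.

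Over all 9 libraries without 33373 and 33377, limma called 0 of 12173 genes (106 at an unadjusted p under 0.05) and camera with a preset correlation called 12 lists. These were not the 12 lists of all 9 libraries. Mesenchymal genes, NF-kappaB targets and hypoxia and glycolysis genes were not called. Luminal markers (mean log2 fold change 0.88, adjusted p = 0.0304; adjusted p = 0.698 with an estimated correlation), adipocyte markers (-1.61, adjusted p = 0.00492; adjusted p = 0.608 with an estimated correlation) and p53 targets (0.11, adjusted p = 0.0468; adjusted p = 0.608 with an estimated correlation) were called. The acute-phase mean was -0.85 in place of -1.56 and the MHC class I mean -0.44 in place of -0.80. Interferon-stimulated genes were lower in 43 of 43 members, with a mean log2 fold change of -1.69 (adjusted p = 4.25e-32; adjusted p = 0.493 with an estimated correlation). Proliferation genes were higher in 28 of 28 members, with a mean of 0.59 (adjusted p = 1.45e-08; adjusted p = 0.608 with an estimated correlation).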
